A study of Capra hircus with 2 samples.

How the data were processed

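Droplet-based single-cell RNA sequencing was used on ovarian granulosa cells, the somatic cells that surround the oocyte in the follicle, of Ji'ning grey goats. The labels give 2 libraries, 1 from goats of high fertility and 1 from goats of low fertility. Per the labels' protocols, the cells were dissociated with a trypsin-like enzyme and the libraries were made with the 10x Genomics 3' kit of the V2 chemistry, which counts transcripts by unique molecular identifiers (UMIs) read from their 3' end. Per the submitters' processing notes, Cell Ranger 2.2.0 was used. The genome build, the annotation, the filter on cells and the program that normalized the values are not given in the sources used here, nor is the number of goats behind each library.

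The authors deposited a table of genes by cells whose values are on a natural log scale. The values show how it was made. In each cell they equal the natural log of 1 plus 10000 times the gene's UMIs divided by the cell's total over all genes. At the smallest value of a cell this formula gave a whole total in 99.9% of the 10451 cells, within 0.0001. Each cell was then given the smallest total at which the total and all of its values were whole; the smallest value stood for 1 UMI in 10442 cells, for 2 UMIs in 4 cells and for 3 UMIs in 5 cells. All 177610 values above 0 came out as whole UMIs at that tolerance. A total can be too low only where all of a cell's counts share a factor, which is most easily missed in the 10 cells with 2 or fewer detected genes.

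The table used here holds 154 complete gene rows and ends within the next row, which was left out; genes beyond it were not analysed here. Of the 154 genes, 117 carry a symbol and 37 only an Ensembl identifier. The RefSeq table of assembly ARS1.2 holds 110 of the symbols, all on chromosome 1, and 108 of the 109 neighbouring pairs follow in rising order there. The genes are therefore 1 stretch of 1 chromosome and no sample of the transcriptome. The table pairs no Ensembl identifiers with symbols, so genes known only by an identifier are not named.

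Each cell was assigned to its library by the prefix of its column name, as the labels describe. UMIs were summed per library and divided by the library's summed totals and multiplied by 1000000 (CPM). Because the totals cover all genes, these CPM refer to the whole library although only 154 genes were analysed. A CPM ratio was given an exact 95% interval from the binomial distribution of the UMIs of both libraries, and a CPM an exact Poisson interval. These intervals cover counting error only. With 1 library per group there is no replicate, so no test between groups was run and no p-value is given. A difference between these libraries cannot be separated from differences between single goats, dissections or library preparations.

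These choices were made before the data were examined. On a log table, genes were to be counted by a difference of 0.5 between the library means of the deposited values. The rule on counts asked for a CPM ratio of 2, a CPM of 50 in the higher library and 20 cells with a count. The rule for named genes took the genes past that count rule, together with genes fixed by name such as FSHR, CYP19A1 and INHA, none of which is among the 154. As no gene passed the count rule, the genes named below were chosen after their values were seen, from the genes with at least 10 CPM in the higher library or at least 100 UMIs in both together. Exceptions are NRIP1 and UPK1B, named as members of fixed lists, and CD96, CD80, IL10RB, IFNAR1 and CD47, taken as immune genes for a test of cells with SAMSN1. Of 22 fixed gene lists only the ovulatory response (ADAMTS1, ALCAM and NRIP1, of 20 genes) and the antioxidant list (SOD1) had members here, and of 13 marker lists only surface epithelium (UPK1B). No cell class could therefore be named, cells were not clustered, and shares of cell classes, comparisons within granulosa-like cells and shares of proliferating cells were not computed. Random lists matched on level were planned over bins of all genes; with so few genes each member was matched to the 10 genes closest in level instead. The planned filter on genes per cell was not applied either, since genes per cell over the whole transcriptome were not known; all deposited cells were kept.

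The UMI counts were worked back only after the data were seen, so every result on CPM is an addition to the planned comparison of deposited values. Some of the settings used on CPM, such as the median of ratios, had been planned. Added alternatives standardised ratios over 8 bins of depth (bounds at 2500, 5000, 7500, 10000, 15000, 20000 and 30000 UMIs per cell), or left out cells above 15000 or below 2500 UMIs; for CCDC80, FILIP1L and ADAMTS1 cells below 7500 UMIs were also taken alone, and for cells with SAMSN1 those below 5000 UMIs. To compare shares of cells with a UMI, the share expected after drawing 2000 UMIs from each cell was calculated from the hypergeometric distribution; cells with fewer were left out, 209 of the high and 132 of the low fertility library. Recovery and ratios were tested on simulated data. With the 154 genes at their means over both libraries and 20 of those above 10 CPM changed 2.5-fold, some up and some down, 99.99% of the cells' totals were recovered exactly. All 20 changed genes passed 2-fold, 0 unchanged genes did, and the interval held the simulated ratio for 44 of the 44 genes at 10 CPM or more. Counts were drawn from Poisson distributions at the same rate per UMI in all cells of a library. The simulation thus held no other differences between cells. It checks the calculation and not how well the intervals hold on real cells. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.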

Results

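Granulosa cells of goats bearing more than 3 kids per birth were compared with those of goats bearing fewer than 2, to describe expression in the follicle at different fertility. The table held 7106 cells of the high fertility library and 3345 of the low fertility library, 10451 in all, beside about 12000 stated for the study. The worked-back totals summed to 63769786 UMIs in the high and 45674506 UMIs in the low fertility library. The median cell held 7214.5 UMIs in the high and 11080 UMIs in the low fertility library, a 1.54-fold difference in depth. Cells ranged from 619 to 102029 UMIs in the former and from 1086 to 137581 UMIs in the latter. Cells of more than 15000 UMIs made up 11.8% of the high and 29.4% of the low fertility library. The 154 genes analysed took 0.971% of the UMIs of the high and 1.09% of those of the low fertility library. A count of 0 allows a level of up to 0.047 CPM in the high and 0.0657 CPM in the low fertility library (3 UMIs).

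**Figure D1:**
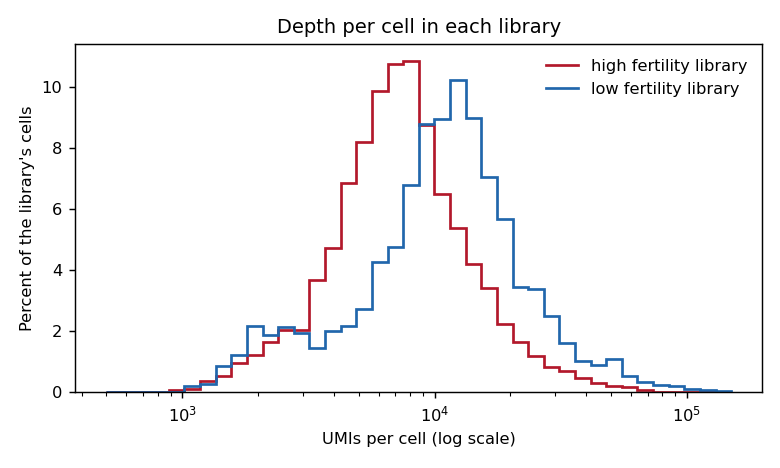
Distribution of UMIs per cell (log scale) as a percent of each library's cells, for the high (red) and low (blue) fertility library. The medians lie at 7214.5 and 11080 UMIs, and both libraries have cells below 2500 UMIs (5.43% and 7.35%).

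On the deposited log scale, 1 of the 154 genes differed by 0.5 or more between the library means. This gene, ENSCHIG00000012599, lies in the table between DZIP3 and NECTIN3, and no symbol was paired with it. Its mean was 2.14 ± 1.76 (SD over 7106 cells) in the high and 2.97 ± 1.61 (SD over 3345 cells) in the low fertility library, a difference of -0.83. No gene was higher by 0.5 in the high fertility library. A difference of 0.5 requires a mean of at least 0.5 in 1 of the libraries, which most of the genes did not reach. FILIP1L, for example, had means of 0.107 in the high and 0.0487 in the low fertility library, and CCDC80 of 0.124 and 0.0745. For such genes the rule could not count a difference of any fold. Only 6 genes differed by 0.1 or more in either direction. These means and SDs are over cells of 1 library each and hold no replicate error.

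The values of ENSCHIG00000012599 fell into a low and a high mode. In the high fertility library 54.5% of the cells lay below 2.5 (exact 95% interval 53.3% to 55.6%), against 32.9% in the low fertility library (31.3% to 34.5%). Cells near that bound, with values from 2 to 3, made up 5.61% and 5.71%. Cells without a UMI of the gene made up 26.1% of the high and 9.84% of the low fertility library. Among the cells above 2.5 the means were close, at 3.926 ± 0.599 (SD over cells) in the high and 3.995 ± 0.626 in the low fertility library. In CPM the gene stood at 2934 in the high and 4164 in the low fertility library, a ratio low over high of 1.42 (1.41 to 1.43). It was higher in the low fertility library in 8 of 8 depth bins.

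**Figure D2:**
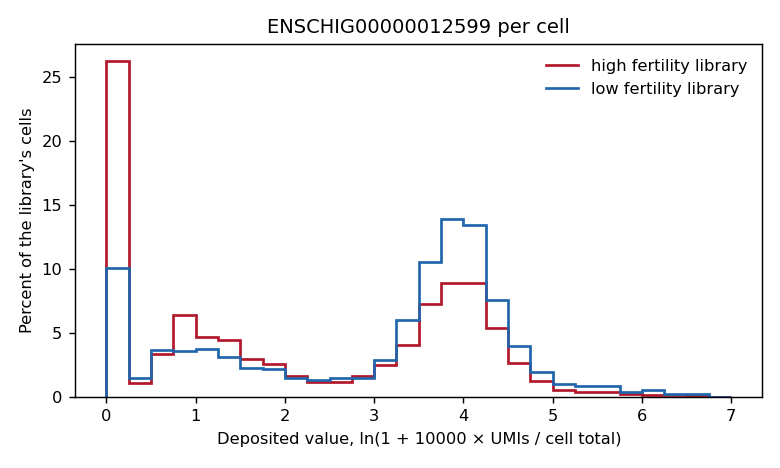
Distribution of the deposited value of ENSCHIG00000012599 per cell, as a percent of each library's cells, for the high (red) and low (blue) fertility library. The cells form modes at 0 to 2 and near 4, and 54.5% of the high but 32.9% of the low fertility cells lie below 2.5.

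FILIP1L, CCDC80, ADAMTS1, ALCAM and DCBLD2 had the highest ratios in favour of the high fertility library among genes with a symbol and at least 10 CPM. FILIP1L, which encodes a filamin A interacting protein, stood at 23.9 against 7.93 CPM, a ratio of 3.02 (2.69 to 3.39). CCDC80, a secreted matrix-associated protein, stood at 37.0 against 12.6 CPM, a ratio of 2.94 (2.68 to 3.23). ADAMTS1, a secreted protease that cleaves versican around ovulation, stood at 13.5 against 6.39 CPM, a ratio of 2.12 (1.85 to 2.43). ALCAM, a cell adhesion molecule, followed at 13.9 against 7.12 CPM, a ratio of 1.96 (1.72 to 2.23). DCBLD2, a transmembrane protein, stood at 18.6 against 11.5 CPM, a ratio of 1.63 (1.47 to 1.81). FILIP1L and ADAMTS1 were higher in the high fertility library in 8 of 8 depth bins, CCDC80 in 7, and ALCAM and DCBLD2 in 6. Without the cells above 15000 UMIs, the FILIP1L ratio was 2.69, that of CCDC80 2.09, of ALCAM 1.71, of ADAMTS1 1.54 and of DCBLD2 1.25. As means over cells the ratios were 2.83 for FILIP1L, 2.12 for CCDC80, 1.90 for ADAMTS1, 1.54 for ALCAM and 1.23 for DCBLD2. In cells below 7500 UMIs, 3766 in the high and 938 in the low fertility library, CCDC80 was not distinguishable between the libraries (ratio 1.15, 0.895 to 1.51), while FILIP1L had a ratio of 2.24 (1.66 to 3.09) and ADAMTS1 of 1.84 (1.17 to 3.05).

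Below 10 CPM, further genes with at least 100 UMIs in both libraries together were 2-fold or more higher in the high fertility library. COL8A1, a chain of type VIII collagen, stood at 9.30 against 3.83 CPM, a ratio of 2.43 (2.05 to 2.89). APP, the amyloid precursor protein, had a ratio of 2.65 (2.02 to 3.52), LSAMP, a cell surface adhesion protein, 2.30 (1.85 to 2.89) and the kinase gene HUNK 2.30 (1.55 to 3.48). With FILIP1L, CCDC80 and ADAMTS1 these made 7 of the 101 genes with 100 UMIs. Some of these ratios lay under 2 in other settings: LSAMP at 1.73 standardised over the depth bins, COL8A1 at 1.89 and HUNK at 1.83 without cells above 15000 UMIs, and HUNK at 1.94 and ADAMTS1 at 1.90 as means over cells. ADAMTS1 also lay at 1.89 relative to the median ratio of abundant genes.

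SOD1, COX17 and MRPS6 were lower in the high fertility library. SOD1, the cytosolic copper and zinc superoxide dismutase, stood at 14.3 CPM in the high and 27.0 CPM in the low fertility library, a ratio low over high of 1.88. COX17, a copper chaperone for cytochrome c oxidase, stood at 53.7 against 94.8 CPM, 1.76 times as high in the low fertility library. MRPS6, a protein of the small mitochondrial ribosomal subunit, stood at 1.33 against 4.25 CPM, a ratio low over high of 3.19 (2.46 to 4.16) on 85 and 194 UMIs. SOD1 and COX17 were higher in the low fertility library in 8 of 8 depth bins, and MRPS6 in 7. MRPL39, of the large mitochondrial ribosomal subunit, had a ratio high over low of 1.21 (1.16 to 1.25) and TOMM70, a receptor for protein import, of 1.22 (1.17 to 1.28). TRMT10C, a subunit of mitochondrial RNase P, had a ratio of 1.02 (0.956 to 1.08). Among the 101 genes, MRPS6 and 1 gene without a symbol were 2-fold or more higher in the low fertility library. Relative to the median ratio of abundant genes, 1.12, MRPL39 stood at 1.08, TOMM70 at 1.09 and TRMT10C at 0.907.

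Of the 44 genes with at least 10 CPM in the higher library, 37 lay between 1.5-fold lower and 1.5-fold higher. The interval of the ratio lay above 1 for 29 genes, below 1 for 9 and held 1 for 6. The median ratio high over low was 1.14. NFKBIZ, a nuclear regulator of the NF-kB response, stood at 156 against 118 CPM (ratio 1.32), the anti-proliferative gene BTG3 at 79.1 against 60.3 CPM (1.31), PROS1, which encodes protein S, at 81.3 against 62.1 CPM (1.31), and the HMG-box gene BBX at 123 against 95.9 CPM (1.29). IFNGR2, a chain of the interferon gamma receptor, stood at 44.6 against 53.8 CPM, a ratio of 0.829. SON, a splicing cofactor, had a ratio of 0.906. CCT8, a subunit of the cytosolic chaperonin, stood at 192 against 178 CPM (1.08), CMSS1 at 88.6 against 87.1 CPM (1.02) and GSK3B, a kinase of Wnt and insulin signalling, at 27.1 against 23.3 CPM (1.17).

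**Figure D3:**
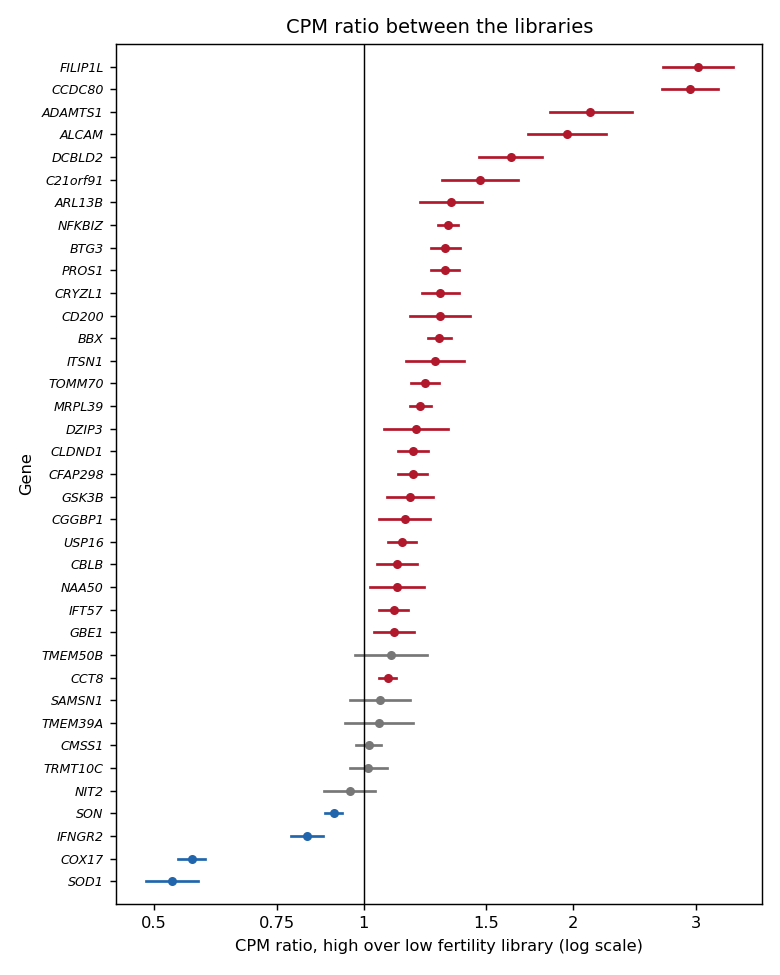
CPM ratio, high over low fertility library (log scale), of the 37 genes with a symbol and at least 10 CPM in the higher library; points are ratios, lines exact 95% intervals for counting error, red above 1, blue below 1 and grey holding 1. FILIP1L (3.02) and CCDC80 (2.94) lie highest and SOD1 (0.531) and COX17 (0.567) lowest.

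Dividing by the median ratio of the 18 genes with at least 50 CPM in both libraries, 1.12 or 0.16 on the log2 scale, left 23 of the 44 genes higher in the high and 21 in the low fertility library, instead of 34 and 10. By construction this division turns every ratio between 1 and 1.12, which was so for 11 genes, among them CCT8 (0.967) and CMSS1 (0.908), so the direction of such small ratios is not settled by these data. FILIP1L, CCDC80, ADAMTS1, ALCAM, DCBLD2, SOD1 and COX17 kept theirs, and relative to that shift the ratios were 2.69 for FILIP1L, 2.63 for CCDC80, 1.89 for ADAMTS1, 1.75 for ALCAM, 1.45 for DCBLD2, 0.474 for SOD1 and 0.506 for COX17.

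The ovulatory response list was represented by ADAMTS1, ALCAM and NRIP1, a nuclear receptor corepressor. NRIP1 stood at 2.02 CPM in the high and 2.21 CPM in the low fertility library, a ratio of 0.915 (0.700 to 1.199). The median log2 ratio of the 2 members above 5 CPM was 1.03, above 100% of 10000 random lists of 2 genes, each drawn from the 10 genes closest in level. With only 10 genes to draw from per member, the random lists repeat a small set of pairs, so the percentage is coarse. With 2 of 20 genes this describes ADAMTS1 and ALCAM rather than the list. The antioxidant list was represented by SOD1 alone. UPK1B, the single marker gene measured, stood at 0.455 CPM in the high and 0.504 CPM in the low fertility library, a ratio of 0.903 (0.505 to 1.63).

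The share of cells with a UMI followed the depth. Of the 44 genes, 37 were detected in a larger share of cells in the low fertility library, and 11 after each cell was reduced to 2000 UMIs. COX17 was detected in 31.3% of the high and 56.7% of the low fertility cells, and in 9.79% and 17.1% after thinning. For SOD1 the shares were 11.4% and 27.4%, and 2.79% and 5.39% after thinning. CCDC80 was detected in 11.7% and 10.7% of the cells, and in 4.31% and 2.36% after thinning. FILIP1L was detected in 10.0% and 6.82%, and in 3.73% and 1.57% after thinning. As no cell class was named, the share that free RNA alone would give is not known for these genes. For 8 of the 44 genes, among them CCT8 and CMSS1, the difference of the deposited log means had the opposite sign to the CPM ratio.

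**Figure D4:**
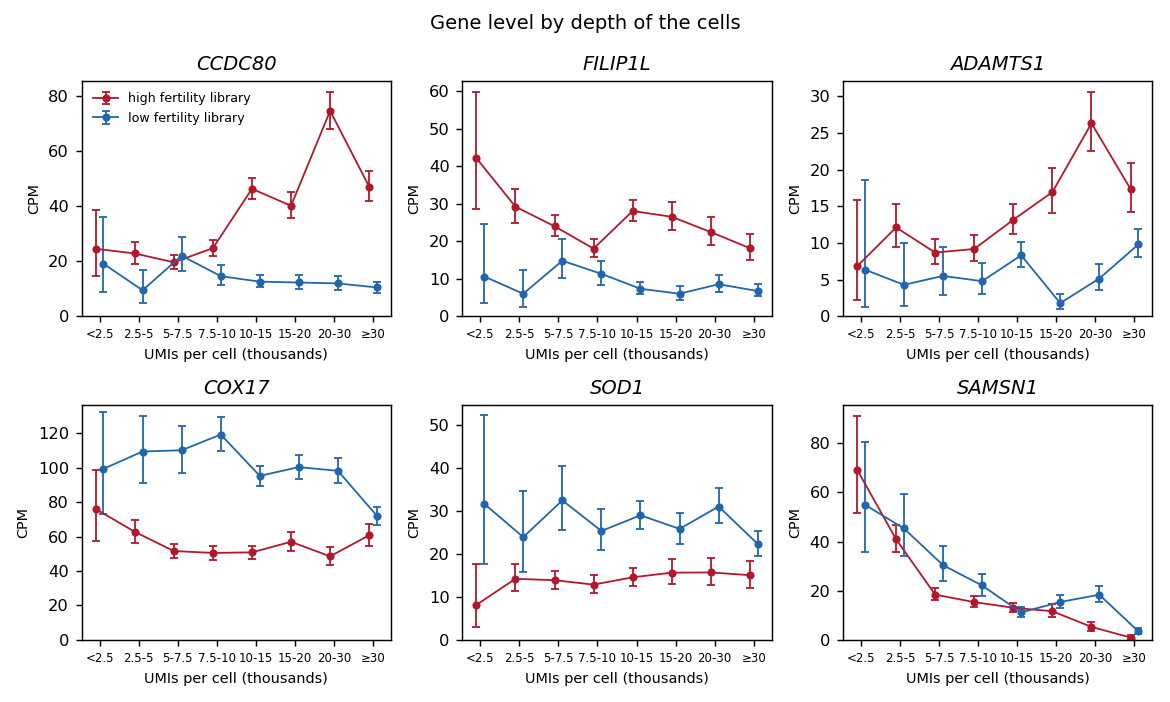
CPM of 6 genes in cells grouped by UMIs per cell (8 bins) for the high (red) and low (blue) fertility library; bars are exact 95% Poisson intervals. CCDC80 reaches 74.6 CPM in high fertility cells of 20000 to 30000 UMIs against 11.9 CPM in the low fertility library, while SAMSN1 is highest below 2500 UMIs in both (69.3 and 55.0 CPM).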

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

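Some of these settings, on summed UMIs with a CPM of 10 or 50 or more and on depth, were chosen after seeing the data; why counts differ between settings was not tested. The planned comparison of deposited log means counted 0 genes higher in the high and 1 in the low fertility library, and the same with cells of 1000 or more UMIs. On the linear scale with a CPM of 50 or more, as means over cells or as summed UMIs, with the median of ratios, with cells of 1000 or more UMIs, and with summed UMIs at a CPM of 200 or at 3-fold, 0 genes were 2-fold higher in the low fertility library, where ENSCHIG00000012599 had a ratio high over low of 0.705 on summed UMIs, 0.617 as a mean over cells and 0.629 with the median of ratios; at 1.5-fold COX17 was counted. In the high fertility library these settings gave 0. With summed UMIs at a CPM of 20 or more the counts were 2 (FILIP1L and CCDC80) and 0, and at 10 or more 3 (with ADAMTS1) and 0. With no filter on low values, means over cells gave 15 and 11 genes, many of them on few UMIs. The median log2 ratio of the 2 ovulatory genes moved from 1.03 to 0.78 as a mean over cells. Of 174 ratios recomputed for 29 named genes in 6 settings, 115 stayed within the counting interval of the reported ratio and 58 left it. Among these 29 genes only CCT8 turned a direction whose interval excluded 1, from 1.08 to 0.967 with the median of ratios, by the division itself. Of the 44 genes with at least 10 CPM, 11 turned by that division, including genes outside the 29 such as IFT57 (1.10, 1.05 to 1.16). Scrublet, totals without abundant genes, a mitochondrial limit and all clustering alternatives were not run, as they rest on genes not analysed here, and no member of the ovulatory list reached a CPM of 50. Many ratios below 10 CPM rest on few UMIs, though that of COL8A1 rests on 593 in the high and 175 in the low fertility library. No setting stands in for a second library per group. No paired analysis was possible because each group has 1 library.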

Other observations

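All tests in this part but that on immune genes were chosen after the result was seen, and of the immune genes the level of CD96 in shallow cells had been seen before. Intervals cover counting error within a library, and cells are not replicates. Where cells with and without a UMI of a gene are compared at matched depth, the interval covers the observed UMIs only. The expected UMIs are taken as fixed there, so these intervals are somewhat too narrow. Cells with a UMI of SAMSN1, an adaptor gene of blood cells, differed from the other cells in several genes, in sizes that were not tested between the libraries. At matched depth, the 583 such cells of the high fertility library held 3.17 times the IFNGR2 expected from cells without SAMSN1 (95% interval 2.93 to 3.44), and the 366 such cells of the low fertility library 3.20 times (2.97 to 3.45). ALCAM was 2.87 and 4.23 times as high in them, and NFKBIZ 1.80 and 1.36 times. PROS1 stood at 0.182 and 0.158 of the level in the other cells, CMSS1 at 0.337 and 0.280, and BBX at 0.418 and 0.440. ENSCHIG00000011680, the most abundant of the 154 genes in the high fertility library at 3586 CPM, stood at 0.655 and 0.623, while ENSCHIG00000012599 was 1.97 and 1.26 times as high.

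Other genes were higher in cells with a CCDC80 UMI, 832 in the high and 359 in the low fertility library. At matched depth COL8A1 was 5.15 times (4.63 to 5.72) and 4.96 times (3.97 to 6.13) as high in them as in the other cells, and DCBLD2 4.32 and 2.14 times. ALCAM was 2.69 and 1.72 times, SAMSN1 1.59 and 1.42 times and PROS1 1.38 and 1.40 times as high. ENSCHIG00000012599 was 1.90 and 1.04 times as high. FILIP1L was 2.82 times (2.58 to 3.07) and 3.27 times (2.72 to 3.90) as high. SOD1 was at 1.11 (0.955 to 1.28) and 0.997 (0.860 to 1.15), COX17 at 1.03 and 0.926 and BBX at 0.981 and 0.959.

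ENSCHIG00000012599 was lower in the high fertility library. A difference in depth per cell is argued against as the whole cause: standardised over 8 depth bins the difference of log means was -0.66, beside -0.83 without. A different makeup of cells and a difference between fertility groups or single goats stay open and were not tested.

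CCDC80, FILIP1L and ADAMTS1 were higher in the high fertility library. Cells of more than 15000 UMIs are argued against as the whole cause, since without them the median of the 3 ratios was 2.09. CCDC80 fell from 2.94 to 2.09, FILIP1L from 3.02 to 2.69 and ADAMTS1 from 2.12 to 1.54. At this bound the argument is weakest for ADAMTS1, which lost much of its excess. The median of 2.09 is the ratio of CCDC80, for which the argument depends on the bound. Below 7500 UMIs CCDC80 was not distinguishable between the libraries, while ADAMTS1 had a ratio of 1.84 (1.17 to 3.05). Doublets stay open, since a pair of typical cells can hold fewer than 15000 UMIs and no doublet caller was run: in cells below 7500 UMIs the median of the 3 ratios was 1.84, with FILIP1L at 2.24 (1.66 to 3.09) but CCDC80 at 1.15 (0.895 to 1.51). That 1 shared cell population carries all 3 genes stays open as well: ADAMTS1 was 3.69 times as high in cells with CCDC80 in the high fertility library, but 1.78 times (1.40 to 2.23) in the low, which neither reaches nor excludes the 2 times set for it, while in cells with FILIP1L it was 3.71 times (3.34 to 4.12) and 3.55 times (2.88 to 4.33) as high. A biological difference between fertility groups also stays open and was not tested, with 1 library each.

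SAMSN1 was highest in shallow cells, at 69.3 CPM below 2500 UMIs against 0.963 CPM above 30000 UMIs in the high fertility library, and at 55.0 against 3.45 CPM in the low. Low depth alone is argued against as the whole cause, since it forbids differences between cells of matched depth. Among cells below 5000 UMIs, those with SAMSN1 held 4.67 times (3.85 to 5.62) the IFNGR2 of the others in the high fertility library. In the low fertility library they held 1.93 times (1.21 to 2.92) on 22 UMIs. Both ratios passed the 1.5 times set against low depth, though the interval in the low fertility library reached below it. Of the genes not set for that test, NFKBIZ was 3.17 times (2.80 to 3.57) and 3.996 times (3.08 to 5.10) as high in these cells. PROS1 stood at 0.120 (0.0441 to 0.262) and 0.194 (0.0235 to 0.702) on 6 and 2 UMIs, and CMSS1 at 0.222 (0.118 to 0.379) and 0.354 (0.0964 to 0.906). In the low fertility library the intervals of ALCAM, at 1.90 (0.517 to 4.86), and BBX, at 0.682 (0.327 to 1.25), held 1. Blood-derived immune cells may be the source. This was examined in cells with SAMSN1 of any depth, 583 and 366, and not in those below 5000 UMIs alone. In the cells of any depth, the summed UMIs of CD96, CD80, IL10RB, IFNAR1 and CD47 were 1.99 times (1.62 to 2.43) and 2.41 times (2.02 to 2.85) as high. As 2 times in both libraries had been set, this source stays open. Without CD96 the sums were 1.80 and 2.39 times as high. Most of that sum is CD47, which many cell types express, while CD96 and CD80 rest on 11 and 10 UMIs in the high and 5 and 4 in the low fertility library, IL10RB was at 1.91 (0.918 to 3.52) and 0.631 (0.205 to 1.47) and IFNAR1 at 1.12 (0.535 to 2.05) and 2.34 (1.36 to 3.74), and the general leukocyte gene PTPRC was not analysed here.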
